A study of Arabidopsis thaliana with 12 samples.

How the data were processed

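Messenger RNA levels were measured by RNA sequencing in 12 libraries from Arabidopsis flowers. Per the labels, flowers of stages 1 to 12 came from the wild type or an XBAT31 mutant, at 22 °C or after 3 hours at 38 °C, with 3 replicates of 9 flowers in each of 4 groups. Libraries were made from poly(A) RNA by the dUTP second-strand method and read in pairs on an Illumina NovaSeq instrument. The strandedness setting used for counting is not given in the sources used here, so reads of overlapping, antisense or closely related genes can count towards a gene. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and the TAIR10 genome, without roles, and do not state the step from StringTie to counts.

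The deposited table holds, for 27715 genes, 2 values per library. The deposited expected counts are estimated counts, rounded to whole numbers and not scaled to depth. How they were made is not stated. Of the values up to 20 in genes with 1 transcript, 47.2% are multiples of 4, where 25% would be without a pile-up, so about 4 counts may stand for 1 fragment, which was not tested. The deposited FPKM values are fragments scaled to transcript length and library depth, made by the authors. Totals ran from 44983198 to 63088433 counts per library, and the number of fragments is not known. No counting interval was drawn from the counts, since they may not be independent reads. Where all libraries of a group were at 0 counts, folds are bounds from a floor of 12 counts per library, which stands for 3 fragments at 4 counts each and covers counting error only. Gene positions are those of the deposited table. Symbols came from a newer annotation, used for names only, which matched 27265 genes (98.4%) and gave a symbol for 9908.

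The comparisons, gene lists, named genes and most alternatives were fixed before the data were examined. The plan set limma on log2(FPKM + 1), with edgeR in its place if the table also held raw counts. The deposited counts were taken as meeting that condition, so edgeR was used. Since how they were made is not stated, the condition is not shown to be met. Counts were fitted in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood test with a mean per group over all 12 libraries (8 residual degrees of freedom). Genes were kept by filterByExpr with a minimum count of 10, which left 23585 and removed 4130, and libraries were scaled by the trimmed mean of M-values. The common dispersion was 0.0631, a biological coefficient of variation of 25.1%. Tests were two-sided with Benjamini-Hochberg adjustment over the genes of a comparison, and a gene passed at an adjusted p below 0.05. The 5 comparisons were heat in the wild type, heat in the mutant, genotype at 22 °C, genotype at 38 °C and the difference of the heat responses, mutant minus wild type. The standard error of a log2 fold change came from the same fit.

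There were 18 gene lists of 382 members: the target and its gene family, heat shock factors, small heat shock proteins, large chaperones and co-chaperones, heat-linked regulators and antioxidant enzymes, endoplasmic reticulum protein folding, thermomorphogenesis and circadian clock, floral organ identity and meristem, tapetum and pollen wall, meiosis, maturing pollen, cell cycle and DNA replication, photosynthesis, jasmonate, abscisic acid and dehydration, auxin, salicylic acid and defence, and reference genes for scaling. Of these members 378 were used. The names of A6 and HSP17.7 differed from the table's and CLV3 and FMO1 were not in it. Lists were tested with limma 3.58.1 (camera, preset correlation 0.01), with adjustment over 90 tests, and again with an estimated correlation. Deposited annotation terms of 15 to 300 tested genes (1010 terms) were tested in the same way, per comparison. Correlations across genes used log2 fold changes. XBAT31 was also tested by exact permutation.

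Named genes followed a rule fixed beforehand. XBAT31, HSFB2A, HSFB2B, HSFA2 and ELF3 were named in every comparison. In each comparison up to 10 genes with the largest rise and up to 10 with the largest fall were eligible among those past the threshold with a symbol and without overlap of the groups' libraries, as were up to 4 members of each list with the smallest p. Members of lists could be named with their values whether or not they passed.

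Alternatives fixed beforehand were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a change of at least 2-fold, only the groups compared, a replicate block, and limma on log2 FPKM with other pseudocounts, filters, scalings and variance trends, and each library was left out in turn. Chosen after seeing the data were counts divided by 4, scaling on reference genes and pollen and photosynthesis means as covariates. A robust quasi-likelihood fit and leaving out the 3 libraries that stood apart were also chosen then. So was the use of limma on log2(FPKM + 1), the plan's test without raw counts, beside edgeR. On simulated data, with changes added to 50 genes per size at 22 °C, edgeR called 27 of 50 genes changed by 2-fold and 40 of 50 changed by 4-fold, and 9 of 125 calls were on unchanged genes, against 50 of 168 for DESeq2. The simulation took 4 counts per fragment, a spread set by the mean level of a gene alone and no libraries that stand apart. These rates need not hold for the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.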

Results

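Polyadenylated RNA was sequenced from flowers of wild-type Arabidopsis and of a mutant in XBAT31, a gene that codes for an ankyrin-repeat protein with a RING domain, the domain of many E3 ubiquitin ligases. Flowers were taken from plants kept at 22 °C or held at 38 °C for 3 hours. Each of the 4 groups had 3 libraries, labelled as biological replicates of 9 flowers each, so that 12 libraries were compared. The labels do not say whether replicates came from separate plants or separate days, and the p-values measure the spread between these samples. The deposited table gave an estimated count and an FPKM value (fragments scaled to transcript length and library depth) for 27715 genes. The wild-type libraries held 48365909, 53789648 and 52861470 counts at 22 °C and 58279959, 63088433 and 53485825 at 38 °C. The mutant libraries held 45139365, 46234847 and 51414141 at 22 °C and 44983198, 53249866 and 52031441 at 38 °C. Low counts pile up at multiples of 4, so the number of sequenced fragments behind a count is not known.

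Temperature parted the libraries first. The first principal component held 33.8% of the variance and placed the 6 libraries at 38 °C apart from the 6 at 22 °C. On the second component, with 14.6%, mutant replicate 2 at 22 °C (-88.3), mutant replicate 1 at 38 °C (-45.3) and wild-type replicate 2 at 38 °C (-43.4) lay away from the others. Marker groups of flower parts differed between libraries of a group. Genes of maturing pollen, as a mean log2 level centred over all libraries, stood at -1.74 in mutant replicate 1 at 38 °C and at 1.25 in wild-type replicate 3 at 22 °C. Photosynthesis genes stood at -1.03 in mutant replicate 2 at 22 °C and between -0.14 and 0.46 in the other 11. Levels are given as the mean ± SD of the 3 libraries of a group (n = 3) in FPKM, and changes as log2 fold changes from edgeR with their standard error (SE).

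The targeted gene was checked first. XBAT31 (AT2G28840, chromosome 2, positions 12378337 to 12380742, plus strand, TAIR10) was lower in every mutant library than in every wild-type library. At 22 °C its level was 95.3, 96.8 and 96.6 FPKM in the wild type and 54.3, 55.7 and 45.3 FPKM in the mutant. At 38 °C it was 109, 110 and 107 FPKM in the wild type and 54.2, 47.5 and 49.4 FPKM in the mutant. The mutant thus held 53.8% of the wild-type level at 22 °C (log2 fold change -0.93, SE 0.08, adjusted p = 8.61e-04) and 46.4% at 38 °C (-1.15, SE 0.08, adjusted p = 6.98e-05). An exact two-sided permutation test gave p = 0.1 at each temperature, the smallest p that 3 against 3 libraries allow. The same exact test stratified by temperature gave p = 0.005, the smallest that its 400 permutations allow. The gene did not pass for heat in the wild type (0.08, SE 0.08, adjusted p = 0.499) or in the mutant (-0.15, SE 0.08, adjusted p = 0.220), though without mutant replicate 3 at 22 °C it passed in the mutant (-0.23, adjusted p = 0.0484). The nature of the mutant allele is not given in the sources used here, and a gene-level value does not show which part of the transcript was left. Of the gene family's other members XBAT32, XBAT33 and XBAT34 passed in no comparison, and XBAT35 fell with heat in the wild type (-0.51, SE 0.13, adjusted p = 0.0141), with an adjusted p of up to 0.0545 without wild-type replicate 2 at 22 °C or at 38 °C. The family as a list passed in no comparison, with adjusted p between 0.176 and 0.815, and its median for heat in the wild type was -0.03, or 0.30 with scaling on reference genes. For heat in the mutant it was -0.15, or 0.09 with that scaling. Adjusted over the list alone, 1 member was higher and 1 lower in the mutant at 22 °C. At 38 °C 1 was lower, and 1 fell with heat in the wild type.

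**Figure D1:**
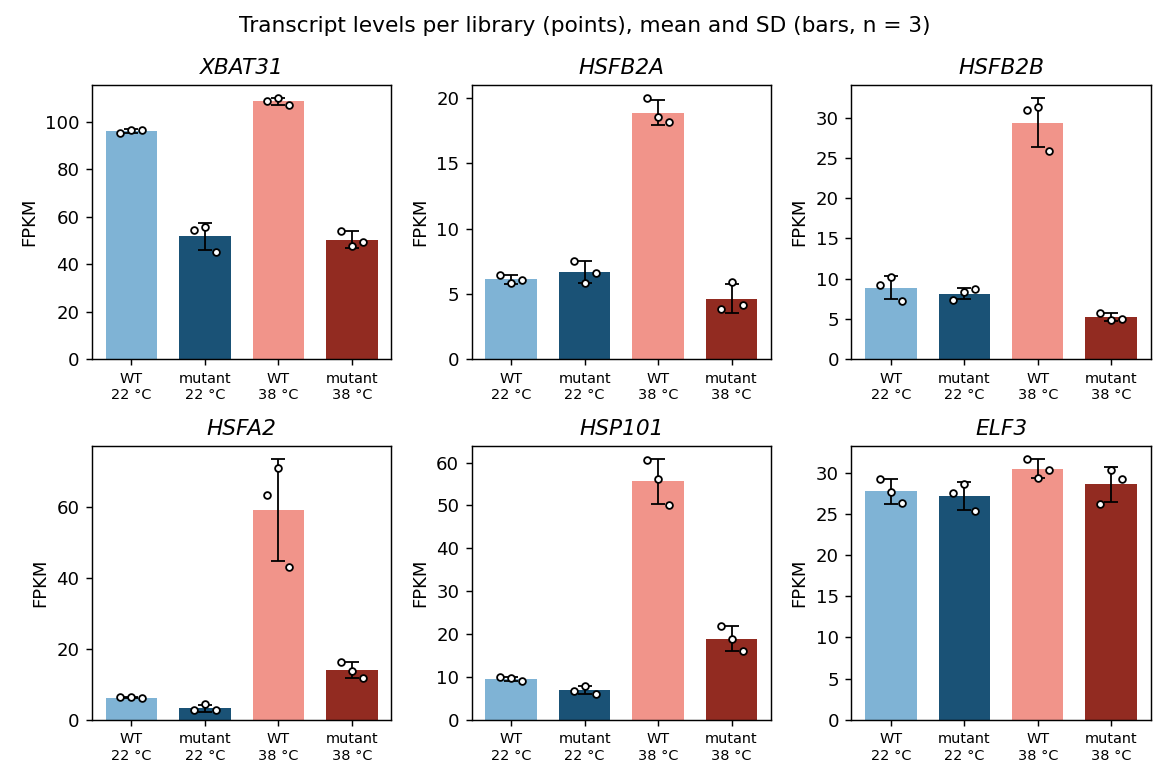
Levels in FPKM (vertical axes, linear from 0) of 6 genes in each library (points, 3 per group) with the group mean (bars) and SD (error bars, n = 3), for the wild type and the mutant at 22 °C and 38 °C. XBAT31 is lower in all 6 mutant libraries. HSFA2 and HSP101 are lower in each mutant library than in each wild-type library at the same temperature, though neither passed in edgeR at 22 °C. HSFB2A and HSFB2B separate the genotypes at 38 °C only.

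The first comparison asked how wild-type flowers respond to heat. Transcripts of small heat shock proteins rose steeply. HSP18.2, a cytosolic small heat shock protein that keeps unfolded proteins soluble, went from 6.11 ± 1.76 FPKM at 22 °C to 838 ± 168 FPKM at 38 °C. HSP22.0 went from 0.820 ± 0.310 to 544 ± 110 FPKM. HSFA2, a transcription factor that prolongs the heat response, went from 6.27 ± 0.128 to 59.2 ± 14.4 FPKM (log2 fold change 3.14, SE 0.22, adjusted p = 4.17e-06). The class B factors HSFB2A (1.53, SE 0.17, adjusted p = 7.71e-05) and HSFB2B (1.63, SE 0.12, adjusted p = 7.60e-06) rose as well. In all, 7241 of 23585 tested genes changed, 3375 upward and 3866 downward, and 1650 of them changed by at least 2-fold. ELF3, a clock and temperature-sensing component, did not pass (27.8 ± 1.49 and 30.5 ± 1.17 FPKM, 0.04, SE 0.08, adjusted p = 0.731).

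Among the heat shock factors 10 of the 19 tested members rose, 1 fell and 8 did not pass (11 and 1 adjusted over the list alone). The list passed (median log2 fold change 0.54, adjusted p = 1.24e-06, and adjusted p = 0.0141 with an estimated correlation). HSFA7A was at 0 counts in all wild-type libraries at 22 °C and at 4.13 ± 0.956 FPKM at 38 °C, which is at least 13.9-fold higher with a floor of 12 counts per library. Of the small heat shock proteins, 15 of the 17 tested members rose, 1 fell and 1 did not pass (15 and 1 adjusted over the list alone), and the list had the largest median of the 18 lists (median log2 fold change 6.95, adjusted p = 6.91e-75, and adjusted p = 4.05e-04 with an estimated correlation). Examples were HSP23.6, which is targeted to mitochondria (7.98, SE 0.46), HSP17.6II (7.05, SE 0.31) and AT2G29500 (7.93, SE 0.29). The chloroplast protein HSP21 was at 0 counts in all libraries at 22 °C and at least 47.0-fold higher at 38 °C with the same floor, and with it at that bound the list's median was 5.55. Of the large chaperones and co-chaperones, 23 of the 31 tested members rose, 0 fell and 8 did not pass (24 and 2 adjusted over the list alone), and the list passed (median log2 fold change 0.79, adjusted p = 4.65e-40, and adjusted p = 0.0224 with an estimated correlation). HSP70 rose from 38.8 ± 1.26 to 576 ± 68.9 FPKM. HSP101, the ClpB-type disaggregase, rose from 9.58 ± 0.423 to 55.6 ± 5.23 FPKM, and HSA32 had a log2 fold change of 3.13, SE 0.13. Close paralogs in these families share sequence, so single values can hold reads of a relative.

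Regulators and antioxidant enzymes linked to heat also moved: 11 of the 22 tested members rose, 2 fell and 9 did not pass (14 and 2 adjusted over the list alone), and the list passed (median log2 fold change 0.87, adjusted p = 9.77e-08, and adjusted p = 0.0294 with an estimated correlation). APX2, a cytosolic ascorbate peroxidase, rose from 0.0327 ± 0.0567 to 25.5 ± 3.83 FPKM. MBF1C, a heat-induced coactivator, rose from 19.3 ± 2.81 to 176 ± 62.5 FPKM. DREB2A, a dehydration and heat transcription factor, rose from 1.85 ± 0.178 to 13.1 ± 2.72 FPKM. GOLS1, which makes galactinol for protective sugars, rose too (4.20, SE 0.24). For protein folding in the endoplasmic reticulum, 11 of the 23 tested members rose, 0 fell and 12 did not pass (11 and 0 adjusted over the list alone), with the DnaJ-type co-chaperone ERDJ3A (1.96, SE 0.14), BIP1 (0.68, SE 0.09) and BIP2 (0.79, SE 0.10) among them (list median log2 fold change 0.37, adjusted p = 3.21e-05, and adjusted p = 0.304 with an estimated correlation). Of the genes of thermomorphogenesis and the circadian clock, 13 of the 28 tested members rose, 3 fell and 12 did not pass (13 and 3 adjusted over the list alone). The clock median was 0.30 (adjusted p = 5.79e-04, and adjusted p = 0.304 with an estimated correlation). The clock genes CCA1 (2.27, SE 0.19), PRR7 (1.29, SE 0.09) and TOC1 (0.87, SE 0.08) rose.

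Abscisic acid and dehydration genes rose in part: 10 of the 25 tested members rose, 3 fell and 12 did not pass (12 and 3 adjusted over the list alone). The abscisic acid median was 0.45 (adjusted p = 2.30e-08, and adjusted p = 0.0728 with an estimated correlation). RD29A (2.96, SE 0.25), the transcription factor ABF3 (2.91, SE 0.18) and HAI1, a phosphatase of the abscisic acid pathway (1.79, SE 0.11), rose. Cell cycle and DNA replication genes went the other way: 1 of the 26 tested members rose, 22 fell and 3 did not pass (1 and 23 adjusted over the list alone). The cell cycle median was -0.66 (adjusted p = 3.29e-09, and adjusted p = 0.397 with an estimated correlation). PCNA1, the replication clamp (-1.11, SE 0.15), CDKB2;2 (-0.85, SE 0.12) and CDKB1;2 (-0.85, SE 0.12) fell. Among maturing pollen genes 0 of the 22 tested members rose, 2 fell and 20 did not pass (0 and 0 adjusted over the list alone). The pollen median was -0.90 (adjusted p = 0.0394, and adjusted p = 0.780 with an estimated correlation), and the list did not pass without wild-type replicate 3 at 22 °C (adjusted p = 0.170) or wild-type replicate 2 at 38 °C (adjusted p = 0.178).

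Most genes that shape the flower did not pass. Of floral organ identity and meristem genes, 0 of the 20 tested members rose, 2 fell and 18 did not pass (0 and 2 adjusted over the list alone). The floral identity median was -0.13 (adjusted p = 0.565, and adjusted p = 0.726 with an estimated correlation, and the median was 0.20 with scaling on reference genes), and SEP2 fell (-0.37, SE 0.07). In the tapetum and pollen wall list, 0 of the 30 tested members rose, 1 fell and 29 did not pass (0 and 0 adjusted over the list alone). The tapetum median was -0.07 (adjusted p = 0.943, and adjusted p = 0.974 with an estimated correlation, median 0.26 with scaling on reference genes). Among meiosis genes 2 of the 20 tested members rose, 3 fell and 15 did not pass (2 and 3 adjusted over the list alone). The meiosis median was -0.07 (adjusted p = 0.888, and adjusted p = 0.965 with an estimated correlation, median 0.27 with scaling on reference genes, test upward), and OSD1, which controls meiotic exit, rose (0.60, SE 0.14). Photosynthesis genes gave 3 that rose, 0 that fell and 15 that did not pass (3 and 0 adjusted over the list alone). The photosynthesis median was -0.12 (adjusted p = 0.826, and adjusted p = 0.965 with an estimated correlation, test upward, median 0.22 with scaling on reference genes). Jasmonate genes were split: 3 of the 24 tested members rose, 3 fell and 18 did not pass (3 and 3 adjusted over the list alone). The jasmonate median was 0.08 (adjusted p = 0.862, and adjusted p = 0.966 with an estimated correlation), with VSP2 higher (1.29, SE 0.33) and AOC3, an enzyme of jasmonate synthesis, lower (-0.71, SE 0.17).

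For auxin, 2 of the 15 tested members rose, 3 fell and 10 did not pass (2 and 4 adjusted over the list alone). The auxin median was -0.25 (adjusted p = 0.274, and adjusted p = 0.512 with an estimated correlation, median 0.08 with scaling on reference genes), with GH3.3 lower (-1.01, SE 0.10). In salicylic acid and defence, 0 of the 17 tested members rose, 4 fell and 13 did not pass (0 and 4 adjusted over the list alone). The defence median was -0.46 (adjusted p = 0.200, and adjusted p = 0.637 with an estimated correlation, and the median was -0.45 with CBP60G at its bound), and EDS1 (-0.60, SE 0.10) and WRKY54 (-1.49, SE 0.36) fell. Of the 10 reference genes commonly used for scaling, 4 fell and 6 did not pass (5 adjusted over the list alone). The reference gene median was -0.23 (adjusted p = 0.0382, and adjusted p = 0.278 with an estimated correlation, median 0.11 with scaling on these genes), with ACT2 lower (-1.13, SE 0.11). The reference list did not pass without any 1 of wild-type replicates 2 (adjusted p = 0.0536) and 3 (0.0504) at 22 °C, wild-type replicates 2 (0.0568) and 3 (0.0842) at 38 °C and mutant replicate 2 at 22 °C (0.0535). Of 1010 deposited annotation terms, 108 passed with the preset correlation and 0 with an estimated one, under which 57 had an unadjusted p below 0.05. Chance alone gives such a p for a share of about 0.05 of the terms. The counts of such terms in each of the 5 comparisons lie near or below that share, so they are no evidence for the terms. In the term for response to heat 72 of 164 genes rose and 17 fell (adjusted p = 7.97e-22). In that for rRNA modification 25 of 41 genes rose and 0 fell (adjusted p = 7.58e-10). The small nucleolar RNA genes gave close values (26 of 44 rose and 0 fell), and selection of poly(A) RNA takes up little of these transcripts. How many genes both groups share was not counted, so they need not be separate results. In that for the proteasome complex 1 of 55 genes rose and 40 fell (adjusted p = 3.13e-06).

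Group libraries did not overlap for 7154 of the 7241 changed genes and for 48.0% of all tested genes, where chance gives 10%. Scaling on the 10 reference genes in place of edgeR's trimmed mean of M-values moved the median of all genes by 0.34 for heat in the wild type, 0.24 for heat in the mutant and -0.10 for the difference of heat responses. Changes are thus relative to that median. With reference scaling 88.5% of 8873 changed genes were higher after heat in the wild type, and in limma on log2(FPKM + 1) 61.5% of 7054, against 46.6% in edgeR with the trimmed mean. Of the 75 named genes that changed with heat in the wild type, 53 passed without any 1 library and 22 did not pass in at least 1 such fit, XBAT35 among them.

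The same comparison in the mutant asked how its flowers respond to heat. Small heat shock proteins rose steeply here too: HSP18.2 went from 4.98 ± 0.653 to 653 ± 77.2 FPKM and HSP22.0 from 0.546 ± 0.155 to 372 ± 62.4 FPKM. HSFA2 rose from 3.26 ± 0.959 to 13.9 ± 2.27 FPKM (log2 fold change 1.99, SE 0.22, adjusted p = 1.84e-04). HSFB2B fell, from 8.12 ± 0.69 to 5.21 ± 0.467 FPKM (-0.75, SE 0.12, adjusted p = 0.00177), and HSFB2A fell (-0.63, SE 0.17, adjusted p = 0.0201), a call that was lost without mutant replicate 1 at 22 °C and without mutant replicates 1 or 3 at 38 °C (adjusted p of up to 0.0779). In all 5875 of 23585 genes changed, 2669 upward and 3206 downward, 1077 of them by at least 2-fold. Which direction was the more frequent turned with the setting: 5814 rose and 995 fell with scaling on reference genes, and 3971 rose and 2129 fell in limma on log2(FPKM + 1). ELF3 did not pass (27.2 ± 1.73 and 28.6 ± 2.1 FPKM, -0.03, SE 0.08, adjusted p = 0.799).

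Among the heat shock factors 7 of the 19 tested members rose, 3 fell and 9 did not pass (8 and 4 adjusted over the list alone), and the list did not pass (median log2 fold change 0.27, adjusted p = 0.0631, and adjusted p = 0.236 with an estimated correlation). HSFA8 rose (0.91, SE 0.14) and HSFA5 fell (-0.84, SE 0.12). Of the small heat shock proteins, 15 of the 17 tested members rose, 1 fell and 1 did not pass (15 and 1 adjusted over the list alone). The small heat shock protein median was 5.51 (adjusted p = 6.91e-75, and adjusted p = 4.05e-04 with an estimated correlation), and HSP21 was at least 25.9-fold higher at 38 °C with the floor of 12 counts (list median 4.69 with it at that bound). Of the large chaperones and co-chaperones, 20 of the 31 tested members rose, 2 fell and 9 did not pass (20 and 2 adjusted over the list alone). The chaperone median was 0.43 (adjusted p = 2.11e-20, and adjusted p = 0.0904 with an estimated correlation), with HSP70 at 27.9 ± 3.05 and 380 ± 55.9 FPKM and the co-chaperone HOP3 higher (2.54, SE 0.14). In the list of regulators and antioxidant enzymes, 5 of the 22 tested members rose, 3 fell and 14 did not pass (8 and 3 adjusted over the list alone). The heat-linked regulator median was 0.33 (adjusted p = 6.95e-04, and adjusted p = 0.145 with an estimated correlation), with GOLS1 (3.13, SE 0.23) and APX2 (7.23, SE 0.76) higher. For endoplasmic reticulum folding, 13 of the 23 tested members rose, 0 fell and 10 did not pass (14 and 0 adjusted over the list alone). The endoplasmic reticulum median was 0.36 (adjusted p = 2.20e-05, and adjusted p = 0.304 with an estimated correlation), with BIP2 (0.82, SE 0.10) and the disulfide isomerase PDIL1-2 (0.71, SE 0.08) higher.

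Of the thermomorphogenesis and clock genes, 13 of the 28 tested members rose, 5 fell and 10 did not pass (14 and 6 adjusted over the list alone). The clock median was 0.24 (adjusted p = 8.98e-04, and adjusted p = 0.304 with an estimated correlation). PRR5 (1.49, SE 0.10) and FKF1 (1.20, SE 0.09) rose, and HY5, a regulator of light signalling, fell (-1.13, SE 0.11). For abscisic acid and dehydration, 10 of the 25 tested members rose, 4 fell and 11 did not pass (13 and 4 adjusted over the list alone). The abscisic acid median was 0.52 (adjusted p = 7.43e-05, and adjusted p = 0.164 with an estimated correlation), with RD29A (3.71, SE 0.26), ABF3 (1.46, SE 0.17) and ABI5 (1.01, SE 0.07) higher. In the cell cycle list, 1 of the 26 tested members rose, 17 fell and 8 did not pass (1 and 19 adjusted over the list alone). The cell cycle median was -0.49 (adjusted p = 1.73e-04, and adjusted p = 0.637 with an estimated correlation), with PCNA1 (-0.77, SE 0.15) and the cytokinesis syntaxin KN (-0.85, SE 0.18) lower. The member that rose was CDKB1;2, a kinase of the G2-to-mitosis step, from 5.64 ± 0.384 to 16.7 ± 1.87 FPKM (log2 fold change 1.45, SE 0.12, adjusted p = 4.67e-05). Among jasmonate genes 8 of the 24 tested members rose, 1 fell and 15 did not pass (8 and 1 adjusted over the list alone). The jasmonate median was 0.56 (adjusted p = 0.00556, and adjusted p = 0.696 with an estimated correlation). LOX3 (0.93, SE 0.22) rose. Without mutant replicate 2 at 22 °C, where this list's mean stood at -0.85, the jasmonate list did not pass (adjusted p = 0.155).

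Of the maturing pollen genes, 0 of the 22 tested members rose, 1 fell and 21 did not pass (0 and 0 adjusted over the list alone). The pollen median was -0.84 (adjusted p = 0.00512, and adjusted p = 0.689 with an estimated correlation), and the list did not pass without mutant replicate 1 at 38 °C (adjusted p = 0.0772), whose pollen mean stood at -1.74. The lists of floral identity (adjusted p = 0.115, 5 fell, 5 adjusted over the list alone), meiosis (adjusted p = 0.129, 4 fell, 4 adjusted over the list alone), tapetum and pollen wall (adjusted p = 0.815, 2 fell, 1 adjusted over the list alone) and auxin (adjusted p = 0.484, 2 rose and 3 fell, 2 and 3 adjusted over the list alone) did not pass. Neither did those of photosynthesis (adjusted p = 0.0699, 2 rose, 0 adjusted over the list alone), salicylic acid and defence (adjusted p = 0.816, 1 rose and 1 fell, 1 and 1 adjusted over the list alone) and the reference genes (adjusted p = 0.0571, 4 fell, 6 adjusted over the list alone). For the tapetum and auxin lists the median, mean and test differed in sign, and with scaling on reference genes the medians of the target family (-0.15 to 0.09), auxin (-0.04 to 0.19), salicylic acid (-0.03 to 0.22) and reference lists (-0.23 to 0.01) changed sign. SEP2 (-0.57, SE 0.07) and ACT2 (-0.65, SE 0.11) fell, and WRKY18, a defence regulator, rose (1.09, SE 0.23). Large falls were seen in ACHT5, an atypical thioredoxin (-3.67, SE 0.28), BMY3, a beta-amylase (-3.38, SE 0.17), and BT5 (-3.29, SE 0.28). Of the annotation terms, 122 passed with the preset correlation and 0 with an estimated one, under which 57 had an unadjusted p below 0.05. In protein refolding 20 of 32 genes rose and 2 fell, in rRNA processing 46 of 91 genes rose and 4 fell and in the proteasome complex 1 of 55 genes rose and 35 fell. Group libraries did not overlap for 5785 of the 5875 genes and for 41.3% of all tested genes, where chance gives 10%.

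How far the responses of both genotypes coincide was taken across genes, which are not independent replicates. The log2 changes with heat in the wild type and in the mutant, which share no libraries, correlated across 23585 genes with Pearson's r = 0.571 and Spearman's rho = 0.589. Calls fell together: 1621 genes rose in both genotypes where 382 would overlap by chance, 2047 fell in both where 526 would, and 69 changed in opposite directions. Of the wild-type calls, 80.4% had a smaller change in the mutant, and of the mutant calls 60.4% had a smaller change in the wild type. Genes picked for passing in a genotype tend to show a smaller change in the other, so neither share by itself shows a weaker response. Examples of genes that passed in both with a smaller change in the mutant were HSP18.2 (7.01 in the wild type and 6.92 in the mutant), HSP70 (3.80 and 3.66), BIP1 (0.68 and 0.65), ABI5 (1.07 and 1.01) and PCNA1 (-1.11 and -0.77). Examples with a larger change in the mutant were HSP22.0 (9.25 and 9.30), RD29A (2.96 and 3.71), BIP2 (0.79 and 0.82) and SEP2 (-0.37 and -0.57). None of these 9 passed for the difference of both responses (adjusted p from 0.288 for RD29A to 0.968 for HSP22.0).

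**Figure D2:**
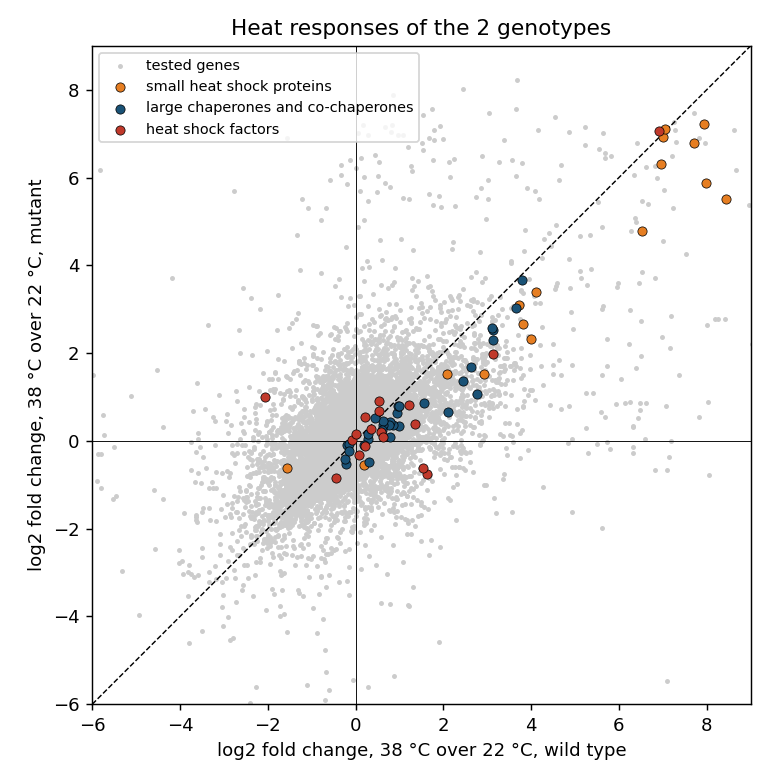
Log2 fold change with heat in the wild type (horizontal axis) and in the mutant (vertical axis) for each tested gene (grey points), with the heat shock factor, small heat shock protein and large chaperone lists in colour and a dashed line of equal change. Axes run from -6 to 9 and 76 genes lie outside them, and most coloured points with a large rise lie below the dashed line.

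The genotypes were then compared at 22 °C, which asks what the mutation changes without heat. Transcripts of ERF104, WRKY70 and TCH4 were higher in the mutant, and that of CDKB1;2 was lower. ERF104, an ethylene response factor, stood at 0.670 ± 0.210 FPKM in the wild type and 22.5 ± 6.78 FPKM in the mutant (log2 fold change 5.01, SE 0.44, adjusted p = 8.15e-04). WRKY70, a defence regulator, stood at 6.53 ± 1.57 and 39.3 ± 1.34 FPKM (2.56, SE 0.21, adjusted p = 6.10e-04). TCH4, a touch-induced cell wall enzyme, stood at 2.97 ± 0.723 and 38.2 ± 22.9 FPKM (3.65, SE 0.40, adjusted p = 0.00230). CDKB1;2 stood at 16.6 ± 0.567 and 5.64 ± 0.384 FPKM (-1.59, SE 0.12, adjusted p = 6.10e-04), and its gene lies 3.77 Mb from XBAT31. Only 45 of 23585 genes passed, 38 higher and 7 lower in the mutant, and 36 differed by at least 2-fold.

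Other genes higher in the mutant were ERF6 (4.53, SE 0.57), ERF13 (2.60, SE 0.28), WRKY33 (3.45, SE 0.39), the zinc finger gene SZF1 (2.21, SE 0.21) and BCS1 (2.25, SE 0.26). The key heat regulators did not pass: HSFA2 stood at 6.27 ± 0.128 and 3.26 ± 0.959 FPKM (-0.98, SE 0.22, adjusted p = 0.220), HSFB2A had a log2 fold change of 0.10, SE 0.17, adjusted p = 0.906, HSFB2B of -0.16, SE 0.12, adjusted p = 0.807 and ELF3 of -0.06, SE 0.08, adjusted p = 0.879. Of the salicylic acid and defence list, 1 of the 17 tested members was higher, 0 were lower and 16 did not pass (8 and 0 adjusted over the list alone), and the list passed (median log2 fold change 0.53, adjusted p = 4.43e-12, and adjusted p = 0.0219 with an estimated correlation). Of the large chaperones, 0 of the 31 tested members were higher, 0 were lower and 31 did not pass (0 and 2 adjusted over the list alone). The chaperone median was -0.15 (adjusted p = 7.70e-05, and adjusted p = 0.497 with an estimated correlation). Photosynthesis genes passed as a list with 0 members past the threshold (0 adjusted over the list alone, median log2 fold change -0.35, adjusted p = 1.26e-06, and adjusted p = 0.512 with an estimated correlation), but not without mutant replicate 2 at 22 °C (adjusted p = 0.127), whose photosynthesis mean stood at -1.03. The heat-linked regulators had 2 higher members (4 higher and 2 lower adjusted over the list alone, median log2 fold change 0.03, adjusted p = 0.0197, and adjusted p = 0.304 with an estimated correlation), and did not pass without wild-type replicate 3 (adjusted p = 0.0683), mutant replicate 1 (0.189) or mutant replicate 3 (0.0563). Meiosis genes had 0 members past the threshold (0 adjusted over the list alone, median log2 fold change 0.21, adjusted p = 0.0289, and adjusted p = 0.541 with an estimated correlation), and did not pass without wild-type replicate 1 (adjusted p = 0.322) or mutant replicate 2 (0.743).

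The other 13 lists did not pass at 22 °C, with adjusted p between 0.0853 for the small heat shock proteins, of which 0 passed (0 adjusted over the list alone), and 0.862 for the reference genes. Median, mean and test differed in sign for the lists of the target family, endoplasmic reticulum folding, clock, floral identity, auxin and reference genes, and the medians of the endoplasmic reticulum and reference lists, both within 0.01 of 0, changed sign with scaling on reference genes. Jasmonate genes had a median of 0.09 and 0 members past the threshold (3 higher adjusted over the list alone). Of the annotation terms, 79 passed with the preset correlation and 0 with an estimated one, under which 25 had an unadjusted p below 0.05. In the term for response to chitin 17 of 123 genes were higher and 0 were lower (adjusted p = 6.46e-21), and in that for ethylene-activated signalling 5 of 40 genes were higher and 0 were lower (adjusted p = 5.19e-06). All 45 genes had group libraries that did not overlap, as did 11.8% of all tested genes, where chance gives 10%. The count was 25 without wild-type replicate 1, 26 without replicate 2, 25 without replicate 3 and 27 without mutant replicate 1, all at 22 °C, and 10 of the 15 named genes passed without any 1 library.

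At 38 °C the comparison of genotypes asks what the mutation changes in heated flowers. Transcripts of the regulators HSFB2A, HSFB2B, HSFA2, MBF1C and DREB2A were lower in the mutant. HSFB2A stood at 18.9 ± 0.985 FPKM in the wild type and 4.64 ± 1.13 FPKM in the mutant (log2 fold change -2.06, SE 0.17, adjusted p = 1.16e-04). HSFB2B stood at 29.4 ± 3.06 and 5.21 ± 0.467 FPKM (-2.54, SE 0.13, adjusted p = 5.47e-06) and HSFA2 at 59.2 ± 14.4 and 13.9 ± 2.27 FPKM (-2.13, SE 0.21, adjusted p = 2.68e-04). MBF1C stood at 176 ± 62.5 and 22.0 ± 8.96 FPKM (-3.03, SE 0.32, adjusted p = 3.40e-04) and DREB2A at 13.1 ± 2.72 and 2.96 ± 0.853 FPKM (-2.17, SE 0.22, adjusted p = 3.33e-04). ELF3 did not pass (-0.13, SE 0.08, adjusted p = 0.359). In all, 2269 of 23585 genes passed, 1028 higher and 1241 lower in the mutant, and 405 differed by at least 2-fold. With scaling on reference genes 495 were higher and 1834 lower, and in limma on log2(FPKM + 1) 1298 were higher and 1092 lower.

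Of the heat shock factors, 3 of the 19 tested members were higher, 4 were lower and 12 did not pass (3 and 8 adjusted over the list alone). The heat shock factor median was -0.32 (adjusted p = 2.30e-05, and adjusted p = 0.0219 with an estimated correlation), and HSFA8 was among the higher ones (1.01, SE 0.14). Small heat shock proteins were lower: 0 of the 17 tested members were higher, 8 were lower and 9 did not pass (1 and 13 adjusted over the list alone). The small heat shock protein median was -1.02 (adjusted p = 2.32e-11, and adjusted p = 0.0219 with an estimated correlation), with AT1G54050 at 111 and 40.9 FPKM (-1.48, SE 0.16) and AT1G07400 at 200 and 71.6 FPKM (-1.52, SE 0.21). Of the large chaperones, 0 of the 31 tested members were higher, 22 were lower and 9 did not pass (0 and 26 adjusted over the list alone). The chaperone median was -0.52 (adjusted p = 9.24e-28, and adjusted p = 0.0376 with an estimated correlation), among them HSP101 (-1.60, SE 0.12), HSP70T-2 (-2.07, SE 0.11), BAG6 (-1.52, SE 0.14) and FES1A (-0.88, SE 0.10). Of the heat-linked regulators, 2 of the 22 tested members were higher, 5 were lower and 15 did not pass (2 and 6 adjusted over the list alone). The heat-linked regulator median was -0.05 (adjusted p = 0.0314, and adjusted p = 0.322 with an estimated correlation). That list did not pass without wild-type replicate 2 (adjusted p = 0.0513), wild-type replicate 3 (0.0663) or mutant replicate 1 (0.199) at 38 °C. Endoplasmic reticulum folding genes did not pass as a list (adjusted p = 0.851), with 3 lower members (3 adjusted over the list alone), among them the membrane-bound transcription factor BZIP28 (-0.78, SE 0.08) and ERDJ3A (-1.25, SE 0.14).

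Defence genes were higher in the mutant: in the salicylic acid list 7 of the 17 tested members were higher, 0 were lower and 10 did not pass (8 and 0 adjusted over the list alone). The defence median was 0.54 (adjusted p = 7.44e-10, and adjusted p = 0.0276 with an estimated correlation, and the median was 0.50 with CBP60G at its bound), with WRKY70 at 4.42 and 28.3 FPKM (2.64, SE 0.21), WRKY18 (1.84, SE 0.23), WRKY40 (3.67, SE 0.64) and EDS1 (0.63, SE 0.10). Of the jasmonate genes, 6 of the 24 tested members were higher, 0 were lower and 18 did not pass (8 and 0 adjusted over the list alone). The jasmonate median was 0.55 (adjusted p = 1.45e-05, and adjusted p = 0.512 with an estimated correlation), with AOC3 at 5.25 and 15.2 FPKM (1.49, SE 0.17). Of the cell cycle genes, 5 of the 26 tested members were higher, 0 were lower and 21 did not pass (8 and 0 adjusted over the list alone). The cell cycle median was 0.31 (adjusted p = 5.37e-06, and adjusted p = 0.512 with an estimated correlation), with CDKB1;2 higher (0.72, SE 0.12). Part of the abscisic acid genes were lower: 2 of the 25 tested members were higher, 9 were lower and 14 did not pass (3 and 9 adjusted over the list alone). The abscisic acid median was -0.14 (adjusted p = 7.14e-04, and adjusted p = 0.287 with an estimated correlation), with HAI1 (-1.31, SE 0.10), HAI2 (-1.45, SE 0.28) and ABI1 (-0.74, SE 0.12), all phosphatases of this pathway, and ABF3 (-1.06, SE 0.17). Clock genes moved both ways: 3 of the 28 tested members were higher, 4 were lower and 21 did not pass (4 and 10 adjusted over the list alone). The clock median was -0.15 (adjusted p = 0.565, and adjusted p = 0.883 with an estimated correlation), with PRR5 (0.95, SE 0.10), FKF1 (0.77, SE 0.09) and CHE (1.01, SE 0.14) higher. The auxin list had 1 member higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.816), IAA3 (1.23, SE 0.23) and GH3.5 (-0.95, SE 0.15). The floral identity (adjusted p = 0.565), tapetum (0.438), meiosis (0.429), maturing pollen (0.151), photosynthesis (0.498) and reference lists (0.534) had 0 members past the threshold. Median, mean and test differed in sign for the target family and endoplasmic reticulum lists, and scaling on reference genes changed the sign of the medians of the endoplasmic reticulum (0.08 to -0.01), auxin (0.00 to -0.09) and reference lists (0.07 to -0.02).

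Large differences outside the lists were seen in ERF104 (0.708 ± 0.114 and 25.5 ± 11.5 FPKM, 5.12, SE 0.43), TCH4 (3.95, SE 0.40), PHI-1 (4.24, SE 0.76) and CAF1a, a deadenylase (3.72, SE 0.45), all higher, and in J11, a DnaJ-domain protein (-2.09, SE 0.30), and NAP, a NAC-type senescence factor (-2.79, SE 0.52), both lower. Of the 38 genes higher in the mutant at 22 °C, 37 were also higher at 38 °C, where 1.66 would overlap by chance. The other pairings were 3 lower at both, XBAT31 among them, and 2 opposite, CDKB1;2 and ARR4. Across all genes the genotype changes at the 2 temperatures correlated with Pearson's r = 0.144 and Spearman's rho = 0.0839. Of the annotation terms, 83 passed with the preset correlation and 0 with an estimated one, under which 56 had an unadjusted p below 0.05. In the term for heat acclimation 0 of 46 genes were higher and 17 were lower (adjusted p = 4.26e-08), and in that for response to chitin 35 of 123 genes were higher and 4 were lower (adjusted p = 3.71e-08).

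Group libraries did not overlap for 2262 of the 2269 genes and for 30.1% of all tested genes, where chance gives 10%. The count was 1016 without wild-type replicate 1 and 1155 without mutant replicate 3, both at 38 °C, and 43 of the 57 named genes passed without any 1 library.

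**Figure D3:**
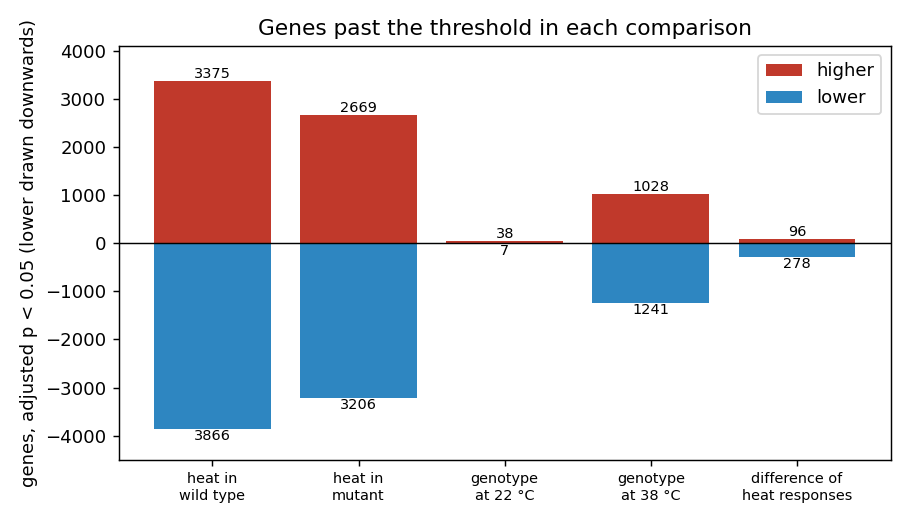
Number of genes past the threshold (adjusted p below 0.05 in edgeR, of 23585 tested), higher (upward bars) and lower (downward bars), for the 5 comparisons. Heat in the wild type gives 3375 higher and 3866 lower genes and genotype at 22 °C gives 38 and 7.

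Whether the heat response itself depends on genotype was tested as the difference of both responses, mutant minus wild type. HSFB2B rose in the wild type and fell in the mutant, a difference of -2.38, SE 0.18, adjusted p = 3.12e-04, and HSFB2A did so too (-2.16, SE 0.24, adjusted p = 0.00430). The heat induction of DREB2A (-2.17, SE 0.31, adjusted p = 0.0115), of the chaperones HSP70T-2 (-1.71, SE 0.15, adjusted p = 7.94e-04) and BAG6 (-1.47, SE 0.19, adjusted p = 0.00860) and of the phosphatase HAI1 (-1.47, SE 0.15, adjusted p = 0.00219) was smaller in the mutant. CDKB1;2 fell in the wild type and rose in the mutant (2.31, SE 0.17, adjusted p = 3.12e-04). The response differed for 374 of 23585 genes, more negative in the mutant for 278 and more positive for 96, and by at least 2-fold for 112. With scaling on reference genes it differed for 518, more negative for 492 and more positive for 26. HSFA2 did not pass (-1.15, SE 0.30, adjusted p = 0.0814), though it did without wild-type replicate 3 at 38 °C (-1.34, adjusted p = 0.0447). Neither did XBAT31 (-0.23, SE 0.12, adjusted p = 0.368) or ELF3 (-0.07, SE 0.11, adjusted p = 0.796).

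Of the 278 genes with a more negative response in the mutant, 110 rose in the wild type and did not pass in the mutant and 56 rose in both. A further 47 rose in the wild type and fell in the mutant, 61 fell in the mutant and did not pass in the wild type and 4 fell in both. Of the 96 with a more positive response, 42 fell in the wild type and did not pass in the mutant and 23 rose in the mutant and did not pass in the wild type. A further 20 fell in the wild type and rose in the mutant, 6 fell in both and 5 rose in both. Heat shock factors were the list whose difference passed with both correlations: 0 of the 19 tested members were more positive, 2 were more negative and 17 did not pass (0 and 4 adjusted over the list alone) (median log2 fold change -0.38, adjusted p = 1.46e-05, and adjusted p = 0.0219 with an estimated correlation). Large chaperones (4 of 31 more negative, 15 adjusted over the list alone, median log2 fold change -0.35, adjusted p = 1.01e-13, and adjusted p = 0.147 with an estimated correlation), small heat shock proteins (1 of 17 more negative, and 5 more negative and 1 more positive adjusted over the list alone, median log2 fold change -0.74, adjusted p = 1.45e-05, and adjusted p = 0.102 with an estimated correlation) and heat-linked regulators (3 of 22, 5 adjusted over the list alone, median log2 fold change -0.20, adjusted p = 5.79e-04, and adjusted p = 0.145 with an estimated correlation) passed with the preset correlation. Jasmonate (0 of 24, 0 adjusted over the list alone, median log2 fold change 0.35, adjusted p = 0.00161, and adjusted p = 0.659 with an estimated correlation) and cell cycle genes (1 of 26 more positive, 1 adjusted over the list alone, median log2 fold change 0.21, adjusted p = 5.00e-04, and adjusted p = 0.659 with an estimated correlation) shifted the other way. The jasmonate list did not pass without mutant replicate 2 at 22 °C (adjusted p = 0.187).

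The abscisic acid list had 2 more negative members (5 adjusted over the list alone). Its test pointed downward while its median was 0.02 (-0.07 with scaling on reference genes) and its mean -0.04 (adjusted p = 0.00534, and adjusted p = 0.322 with an estimated correlation), and it did not pass without replicate 3 at 22 °C of the wild type (adjusted p = 0.0759) or of the mutant (0.0534). Meiosis genes (median log2 fold change -0.33, adjusted p = 0.0366, and adjusted p = 0.566 with an estimated correlation) had 0 members past the threshold (0 adjusted over the list alone). That list did not pass without wild-type replicate 1 (adjusted p = 0.15) or mutant replicate 2 (0.298) at 22 °C, or without wild-type replicates 2 (0.0536) and 3 (0.0709) or mutant replicates 2 (0.0951) and 3 (0.0678) at 38 °C. The other 10 lists did not pass, with adjusted p between 0.0691 for photosynthesis and 0.816 for the tapetum. Of the endoplasmic reticulum list 2 members were more negative (2 adjusted over the list alone), of the auxin list 1, GH3.5, was more negative (1 adjusted over the list alone), and of the clock list 2 were more positive and 1 more negative (3 and 2 adjusted over the list alone). Median, mean and test differed in sign for the endoplasmic reticulum, clock, tapetum and maturing pollen lists, and scaling on reference genes changed the sign of the endoplasmic reticulum (0.06 to -0.04), pollen (0.05 to -0.06) and reference medians (0.07 to -0.03). Beyond the lists, J11 (-2.92, SE 0.41) and EXL2 (-1.78, SE 0.21) were more negative and SPX1, a phosphate sensor (1.32, SE 0.15), ARR4 (1.27, SE 0.14) and ARR7 (1.56, SE 0.19), response regulators of cytokinin signalling, more positive. Of the annotation terms, 104 passed with the preset correlation and 0 with an estimated one, under which 37 had an unadjusted p below 0.05, and in the term for heat acclimation 0 of 46 genes were more positive and 5 were more negative (adjusted p = 5.70e-05).

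The number of genes with differing responses moved with single libraries. Without 1 library it ranged from 60 to 499. It was 94, 60 and 173 without wild-type replicates 1, 2 and 3 at 22 °C, and 75, 126 and 241 without those at 38 °C. It was 111 and 186 without mutant replicates 1 and 2 at 22 °C and 160, 120 and 87 without mutant replicates 1, 2 and 3 at 38 °C. The count was 24 without the 3 libraries that stood apart on the second component. Of 34 named genes, 12 passed without any 1 library: HSFB2A, HSFB2B, DREB2A, HSP70T-2, BAG6, J11, EXL2, HAI1, CDKB1;2, ARR4, ARR7 and SPX1.

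**Figure D4:**
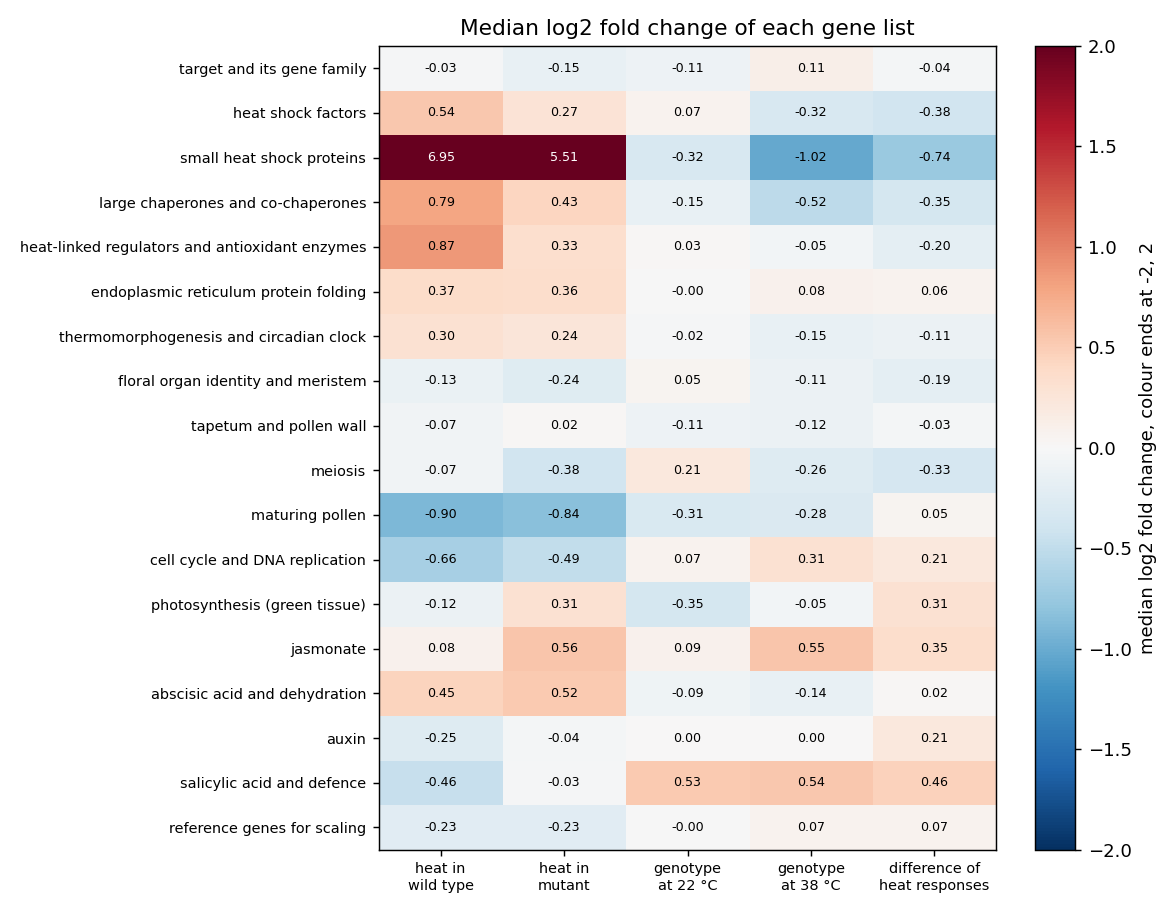
Median log2 fold change of each of the 18 gene lists (vertical) in the 5 comparisons (horizontal), as colours that saturate at -2 and 2. Small heat shock proteins stand at 6.95 and 5.51 with heat in the wild type and in the mutant (5.55 and 4.69 with HSP21 at its bound) and at -0.74 for the difference, and with scaling on reference genes 7 of the wild-type heat medians change sign.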

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

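The tests of explanations for the patterns below were chosen after the results were seen, and the counts over splits of the samples before. The heat response differed between genotypes by edgeR's test of the difference for 374 genes, 34 of them named here with the log2 difference, mutant minus wild type. The response was more negative in the mutant for NAP (-3.28), J11 (-2.92), HSFB2B (-2.38), DREB2A (-2.17), HSFB2A (-2.16), DYL1 (-2.11), RLP30 (-2.11), MBF1C (-2.06), OXS3 (-2.04), EXL2 (-1.78), HSP70T-2 (-1.71), BAG6 (-1.47), HAI1 (-1.47), ABF3 (-1.46), AT1G54050 (-1.40), ERDJ3A (-1.14), HSP101 (-1.09), GH3.5 (-0.98), WRKY39 (-0.87), HSA32 (-0.84), BZIP28 (-0.69), TOC1 (-0.54). It was more positive for CDKB1;2 (2.31), ARR7 (1.56), RR5 (1.55), ULI3 (1.55), FH3 (1.42), SPX1 (1.32), EXL5 (1.31), ARR4 (1.27), TCH2 (1.22), G3Pp1 (1.19), PRR5 (0.75), FKF1 (0.67). Of these 34, 12 passed without any 1 library and 22 did not pass without at least 1.

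The heat shock factor list was more negative in the test of the difference, mutant minus wild type, with both correlations (adjusted p = 0.0219 with an estimated one). The small heat shock protein and large chaperone lists passed with the preset correlation only (adjusted p = 0.102 and 0.147 with an estimated one). Of single members, 2 of 19 heat shock factors, 1 of 17 small heat shock proteins and 4 of 31 large chaperones were more negative and 0 were more positive. Over all 67 tested members the median difference was -0.41 (the same with genes at 0 counts in a group at their bound), and 54 were below 0. Trying another scaling cannot decide whether the scaling of the libraries is the cause, since it shifts all genes about alike. Scaling on reference genes moved the median of all genes by -0.10 for the difference, from 0.03 to -0.07, and so shifted these members with the rest. Their median was then -0.50 (95% bootstrap interval over members, which are not independent, -0.73 to -0.40). That interval does not cover error of the scaling. The members' median lay below that of all genes with both scalings. A difference in flower stage or tissue makeup is argued against as far as pollen and photosynthesis genes track it, since the median was -0.42 (-0.56 to -0.28) with their means as covariates.

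For most members of these lists a uniformly smaller heat response in the mutant cannot be told apart from an effect on single genes. With 1 common factor between both responses, at best 0.83, 6 of the 67 members (8.96%) departed from it at an adjusted p below 0.05 over the members, all lower: HSFB2A, HSFB2B, HSP70T-2, BAG6, HSP101 and AT1G54050. HSFB2A and HSFB2B rose in the wild type and fell in the mutant, which no factor from 0 to 1 gives. The fall of HSFB2A was lost without some single libraries. Without 1 library 4 to 9 members departed. The other members do not decide between both. An effect of the XBAT31 mutation on heat shock factor transcripts may add to this. That is a hypothesis drawn from these data and was not tested, and other differences between the plants stay open.

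Of the genes higher in the mutant at 22 °C, 37 were also higher at 38 °C, ERF104, TCH4 and WRKY70 among them, with a median log2 fold change of 2.25 at 22 °C. These genes were picked for that difference, so their levels do not test it. Cis effects, those of variants linked to the XBAT31 locus on nearby genes, are argued against for most of them. Of the 37, 4 (10.8%, upper bound 25.4%) lie within 5 Mb of that locus, against 9.62% of all tested genes (Fisher's exact two-sided p = 0.778). Gene positions cannot test an effect of linked variants on distant genes, which stays open. For the 7 genes lower in the mutant at 22 °C, effects of such variants cannot be told apart from other effects of the mutation. Besides XBAT31 itself, 3 of the other 6 (50%, 95% exact binomial interval 11.8% to 88.2%) lie within 5 Mb: DML1, CDKB1;2 and AT2G41640, the last of which was named after its values were seen. For the 37 higher genes the median was 2.40 with the pollen and photosynthesis covariates (95% bootstrap interval over these genes, which are not independent, 1.77 to 2.87). Differences in these marker means thus do not account for it. Because the genes were picked for a difference at both temperatures, this does not decide on flower stage or tissue makeup beyond these markers. Handling or wounding of mutant flowers could raise such genes and cannot be told apart from genotype, because no sample parts harvest from genotype: the jasmonate median was 0.0900 at 22 °C and 0.55 at 38 °C.

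For the difference of heat responses, 9 of 100 splits of the samples, the real one included, gave as many genes as the real 374, and the highest other gave 1115, so these splits do not exclude chance. They do not argue for it either. All 9 kept the genotypes whole at 38 °C and so carried the genotype difference there into the test, which points to a structure of the samples. Splits that mixed genotypes at 38 °C gave at most 8 genes, and these add that difference to the spread within groups, so whether chance alone gives 374 genes stays open. For the other comparisons 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. The real and the highest other counts were 7241 and 1 for heat in the wild type, 5875 and 2 for heat in the mutant, 45 and 1 for genotype at 22 °C and 2269 and 23 for genotype at 38 °C.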

How the results depend on the processing

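The settings chosen after seeing the data were the covariates, leaving out the 3 libraries that stood apart, reference gene scaling, counts divided by 4, the robust fit and limma beside the counts. Named genes were refitted in limma with a pseudocount of 0.1 or median-of-ratios scaling, in edgeR with a replicate block or counts divided by 4, and without each library. None that had passed changed sign there. Of genes that had not passed, ELF3 for heat in the mutant was 0.0707 in limma with a pseudocount of 0.1. It ranged from -0.0946 to 0.0316 without 1 library, and HSFB2A at 22 °C ranged from -0.00358 to 0.20; the cause was not tested. The 40 gene list results past the threshold were retested with an estimated correlation, a replicate block or counts divided by 4. They were also retested in limma with median-of-ratios scaling or quantile normalization. For named genes and these lists together, 1113 values under these settings kept their direction and side of the threshold. A further 101 kept the direction but no longer passed and 1 newly passed. This was HSFA2 for the difference of heat responses, at -1.23 in limma with median-of-ratios scaling (adjusted p from 0.0447 to 0.199 over its alternatives). For the lowest and highest values of named genes without 1 library these numbers were 448, 86 and 2. XBAT31 passed at both temperatures under each of the settings used for named genes.

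Counts of genes moved as follows. With a change of at least 2-fold required, the counts were 1650 for heat in the wild type, 1077 for heat in the mutant, 405 for genotype at 38 °C and 112 for the difference of heat responses, since fewer genes meet both limits. With only the groups compared, heat in the mutant gave 3721. The same cut gave 7181 for heat in the wild type, so fewer samples alone do not account for it, and the cause was not tested. DESeq2 gave 247 for genotype at 22 °C, 4035 at 38 °C and 1842 for the difference; the cause was not tested. The covariates gave 3826 for genotype at 38 °C and 627 for the difference; the cause was not tested. For the difference, a replicate block gave 128 in edgeR and 130 in limma, and leaving out 3 libraries gave 24, with fewer samples. Replicate numbers do not pair the libraries: same-number correlations ran from -0.28 to 0.27, and 4 of 12 libraries matched their own number best.

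Without 1 library the counts ranged from 25 to 52 for genotype at 22 °C, 1016 to 2713 at 38 °C and 60 to 499 for the difference. Each fit had fewer samples, but the highest of these counts lay above those with all libraries, and the cause was not tested. Heat gave 5139 to 7894 in the wild type and 4017 to 5726 in the mutant.

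With an estimated correlation, 4, 1, 1, 4 and 1 gene lists passed for heat in the wild type, heat in the mutant, genotype at 22 °C, genotype at 38 °C and the difference. In each, 0 annotation terms passed, and 57, 57, 25, 56 and 37 had an unadjusted p below 0.05 in limma's camera, near or below the share of 0.05 that chance gives. For heat in the wild type the estimated correlation ran from -0.108 for the target family to 0.930 for photosynthesis. It lay above the preset 0.01 for all lists but the target family, heat shock factors and floral identity. For the heat shock factors it was -0.00418, and their unadjusted p in camera still went from 1.80e-07 to 4.70e-04. A higher correlation thus cannot account for all of the change, and the rest was not tested. At 22 °C median-of-ratios scaling in limma gave 3 lists; the cause was not tested. Pearson's r of both heat responses was 0.731 and Spearman's rho 0.779 over genes called in at least 1 genotype. In limma with a pseudocount of 0.1 r was 0.701. The cause of either was not tested. Without 1 library r ranged from 0.458 to 0.525, below the 0.571 with all libraries. These fits also kept more genes, 23967 to 24053 against 23585, so the drop cannot be laid to single libraries alone. Depth limits genes with low counts, and 4130 genes were not tested.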

Other observations

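The groups below were looked at after the results were seen. Type-A response regulators, which dampen cytokinin signalling, were taken up because ARR4 and ARR7 passed for the difference, and no test was run on the group. Of 8 tested, 3 fell and 0 rose in the wild type (median log2 fold change -0.58), and 5 rose and 0 fell in the mutant (0.46). The difference passed for 4, ARR4, RR5, ARR6 and ARR7, all more positive in the mutant, and ARR4 and ARR7 passed without any 1 library (median over the 8 genes 1.23). RR3, ARR9, ARR15 and RR16 did not pass for the difference. At 38 °C 4 were higher in the mutant and at 22 °C 1, ARR4, was lower.

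Transcripts of the mitochondrial genome rose with heat for 87 of 111 genes in the wild type (median 2.68) and for 34 in the mutant (1.15), and the difference passed for 6, all more negative in the mutant. Their share of all counts was 0.0708% at 22 °C and 0.167% at 38 °C in the wild type and 0.0876% and 0.0998% in the mutant. Small nucleolar RNAs rose for 26 of 44 genes in the wild type (1.51) and for 15 in the mutant (0.98), and the difference passed for 0 (-0.32). Of 89 chloroplast genome genes 7 rose and 1 fell in the wild type and 6 rose and 1 fell in the mutant. Selection of poly(A) RNA takes up little of these transcripts, so the values describe the selected RNA.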
